A study of Drosophila melanogaster with 32 samples.

How the data were processed

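RNA was measured by sequencing in brains of Drosophila melanogaster larvae of instar 3, with 500 brains per preparation. In each preparation 10% of the homogenate gave the input library, which samples the whole brain. The remainder was immunoprecipitated with antibodies to GFP, which were directed at the ribosomal protein RpL10Ab fused to GFP and expressed from the driver ipcGal4, and this gave the IP library. Preparations were either wild type or carried the ato1 allele, described in the labels as a loss of function of ato. The 4 groups (wild-type input, ato input, wild-type IP and ato IP) had 2 replicates each, and each replicate had been sequenced in 4 runs, which gives 32 runs.

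The deposited values were raw counts per gene and run, made by the authors with TopHat2 2.0.12 and featureCounts 1.4.4 according to the submitters' processing notes. Per the file headers, reads on dm3 were counted over exons with a minimum mapping quality of 5 and with no option for strand, read pairs, multiple mapping or overlapping genes. Reads from a gene and from an antisense or overlapping partner therefore cannot be told apart, and reads shared between near-identical copies, such as the Hsp70 and Sgs paralogs, were counted in a way the headers do not fully state. Among the genes named, exons overlapped those of another gene for 26.6% of Vmat, 23.0% of RpS15Ab, 18.9% of IFa, 16.5% of HP1c, 16.4% of Shab and 16.1% of crq, and for less than 15% of the others. Even values outnumbered odd ones among low counts (19755 entries of 2 against 7744 of 3). Runs of a library also differed by more than independent counts would, with a chi-square per degree of freedom of 1.78 to 1.92. Both patterns go with separate counts of both ends of a fragment. Counting intervals and floors treat every count as independent, so the intervals would then be too narrow and the lower bounds too high. They do not cover the spread between replicates. The intervals of slopes and list medians come from 10000 bootstrap draws over genes (2000 for the slope) and do not cover that spread either.

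The table held 14161 genes. Names were compared with a table of current names (assembly Release 6 plus ISO1 MT), from which no coordinates were taken: 10669 were current symbols, 2062 matched by locus tag, 1181 matched by synonym and 249 did not match. In 5 entries the name had been turned into a date. Symbols are printed as deposited, with the current name where it helps, and coordinates are those of the deposited table in dm3, counted from 1.

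The 4 runs of each replicate were summed to 8 libraries of 7780123 to 12238648 counts. Runs were not treated as replicates: the chi-square per degree of freedom was 1.78 to 1.92 between runs of a library and 9.7 to 34.1 between replicates of a group. A count of 3 in a single library corresponds to 0.245 to 0.386 CPM, the count scaled to a common library size. CPM values were scaled by TMM factors.

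Differential abundance was tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM factors and quasi-likelihood F tests in 1 model over the 4 groups. Adjusted p-values follow Benjamini and Hochberg over 10224 genes, with a threshold of 0.05, and the common biological coefficient of variation was 0.203. The 5 comparisons were IP against input in wild type, IP against input in ato, ato against wild type in the IPs, ato against wild type in the inputs, and the difference of the IP-over-input ratio between genotypes (an interaction term). Log2 fold changes are given with their standard error (SE), and n is 2 libraries per group throughout. An exact permutation test of 2 against 2 libraries cannot go below 0.33 (two-sided), so none was used. A fold against a group with 0 counts was computed from counts summed over the 2 libraries of each group. It was set against a floor of 3 counts in that sum and is written as a lower bound. Where the lower group held 1 to 3 counts, the ratio of summed counts is given with a 95% counting interval.

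Before the data were examined, the groups, the tests, 35 gene lists, all but 2 of the alternatives and the rule for named genes were fixed. Lists were tested with camera of limma 3.58.1, with an inter-gene correlation preset at 0.01 and again with the correlation estimated. The estimated form also tests on the residual degrees of freedom of 8 libraries in 4 groups, far fewer than the preset form uses. Adjusted p-values are over the 32 lists that had at least 3 tested members. Mitochondrially encoded transcripts (0 genes in the table), replication-dependent histone genes (1 of 111 tested) and the male dosage compensation RNAs roX1 and roX2 (2 genes) were not tested as lists. Of the members in the table, 53 of 281 small nuclear and nucleolar RNA genes and 61 of 77 respiratory chain genes passed the low-count filter. Some genes stand in more than 1 list, among them dac, eya, tll, dap, sens and CadN.

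Named genes had an adjusted p below 0.05, a mean of at least 10 CPM in the higher group (for the interaction, in the highest of the 4 groups) and both replicates of 1 group above both of the other (for the interaction, judged on log2 IP over input of replicates with the same number). They were ranked by fold change, and the first 10 in each direction were taken, or the first 5 for IP against input in ato and for ato against wild type in the inputs. Up to 4 members of each list with the smallest adjusted p below 0.05 were added, without a minimum level. Where fewer than 5 genes passed in a direction, the 5 with the smallest unadjusted p are given. The genes ato and RpL10Ab are always named. The text gives a part of the list members, preferably those whose call held under every alternative, and the few genes named outside this rule were chosen after their values were seen.

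IP and input with the same genotype and number came from 1 homogenate, as the protocol in the labels and their replicate numbers state, and these numbers pair the libraries for IP against input and for the interaction. Between genotypes only a number is shared. The replicate differences of paired libraries correlated across genes at 0.096 in wild type and 0.165 in ato, and between other groups at -0.055 to 0.06. The model without the pairing was fixed in advance, and the homogenate as a block was an alternative.

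Alternatives were DESeq2 size factors, library totals, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a filter of more than 5 CPM in at least 2 libraries, only the groups compared, the replicate block, 1 run per library, and leaving out each library in turn. With 1 library left in a group, that library was assumed to vary like the others. The remaining 2 alternatives were added after seeing the data: counts halved, and a per-library loess correction (span 0.5) of log2 CPM (prior count 2) for exon length. The length correction was centred again on the TMM scale after a first version had shifted all genes.

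The model was tested on simulated counts for 9735 genes. For ato against wild type in the IPs it recovered 10.4%, 67.7% and 83.1% of simulated changes of 1.5, 2 and 4-fold, with 9 false calls. For ato IP against ato input it recovered 11.9%, 64.6% and 80%, with 14 false calls. For the interaction it recovered 3%, 18.5% and 69.2%, with 7 false calls. The false calls made up 7.89%, 12.1% and 10.6% of all calls in these 3 comparisons, against the nominal 5%. The 2 comparisons without simulated changes had 1 and 3 false calls. A simulated length trend gave 435 calls before the length correction and 0 after it.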

Results

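Ribosome-bound RNA was sequenced beside whole-brain RNA in Drosophila larvae of instar 3, in wild type and in ato mutants. The driver ipcGal4 expressed the ribosomal protein RpL10Ab fused to GFP, and the series names T4 and T5 neurons, the motion-detecting neurons of the optic lobe, as the cells whose ribosomes were pulled down. The gene ato encodes the proneural transcription factor Atonal. Each of the 4 groups (wild-type input, ato input, wild-type IP and ato IP) had 2 libraries, and each library came from 500 brains.

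The wild-type inputs held 12238648 and 10099533 counts, the ato inputs 8193052 and 9887284, the wild-type IPs 8904370 and 7780123, and the ato IPs 8086583 and 8084872. At least 1 count was seen for 10368 to 10899 genes in the inputs and for 11774 to 12533 genes in the IPs. The translation elongation factor gene Ef1alpha48D took the largest share of each input (2.62% to 2.90%), and the noncoding RNA gene noe took the largest share of each IP (2.22% to 4.85%). Replicates correlated across genes at 0.982 for wild-type input, 0.970 for ato input, 0.963 for wild-type IP and 0.958 for ato IP, where genes are not independent replicates. The leading principal component held 49.7% of the variance and separated the inputs from the IPs, and the next held 24.6% and separated wild type from ato.

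The transcript of ato itself was not called in any comparison. It lies on chromosome 3R at 4103514 to 4104996 in dm3, and its mean level was 12.8 ± 0.0827 CPM (SD, n = 2) in wild-type input, 15.3 ± 0.392 in ato input, 14.9 ± 3.13 in wild-type IP and 12.1 ± 1.55 in ato IP. The log2 change from wild type to ato was -0.29 ± 0.30 (SE) in the IPs (edgeR adjusted p = 0.701) and 0.25 ± 0.30 in the inputs (adjusted p = 0.671). From input to IP it was 0.21 ± 0.30 in wild type (adjusted p = 0.611), which turned to -0.01 without wild-type IP 2, and -0.33 ± 0.30 in ato (adjusted p = 0.441). The ato1 allele is known for base changes in the coding sequence, so the transcript level neither checks nor contradicts the genotype. RpL10Ab, whose count includes any reads of the tagged copy, was 1.48-fold higher in the wild-type IP than in its input (log2 0.57 ± 0.21, adjusted p = 0.0409). That call was lost without wild-type input 1 (adjusted p = 0.109), wild-type input 2 (0.195) or wild-type IP 2 (0.458). In ato the RpL10Ab value was 0.40 ± 0.21 (adjusted p = 0.158), which passed with the DESeq2 Wald test (0.0454) and with the length correction (0.0046) but with no other alternative. RpL10Ab was not called between genotypes, at 0.11 ± 0.21 in the IPs (adjusted p = 0.862) and 0.27 ± 0.21 in the inputs (0.473). The IP value turned to -0.19 without wild-type IP 1 and to -0.06 without ato IP 2.

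**Figure D1:**
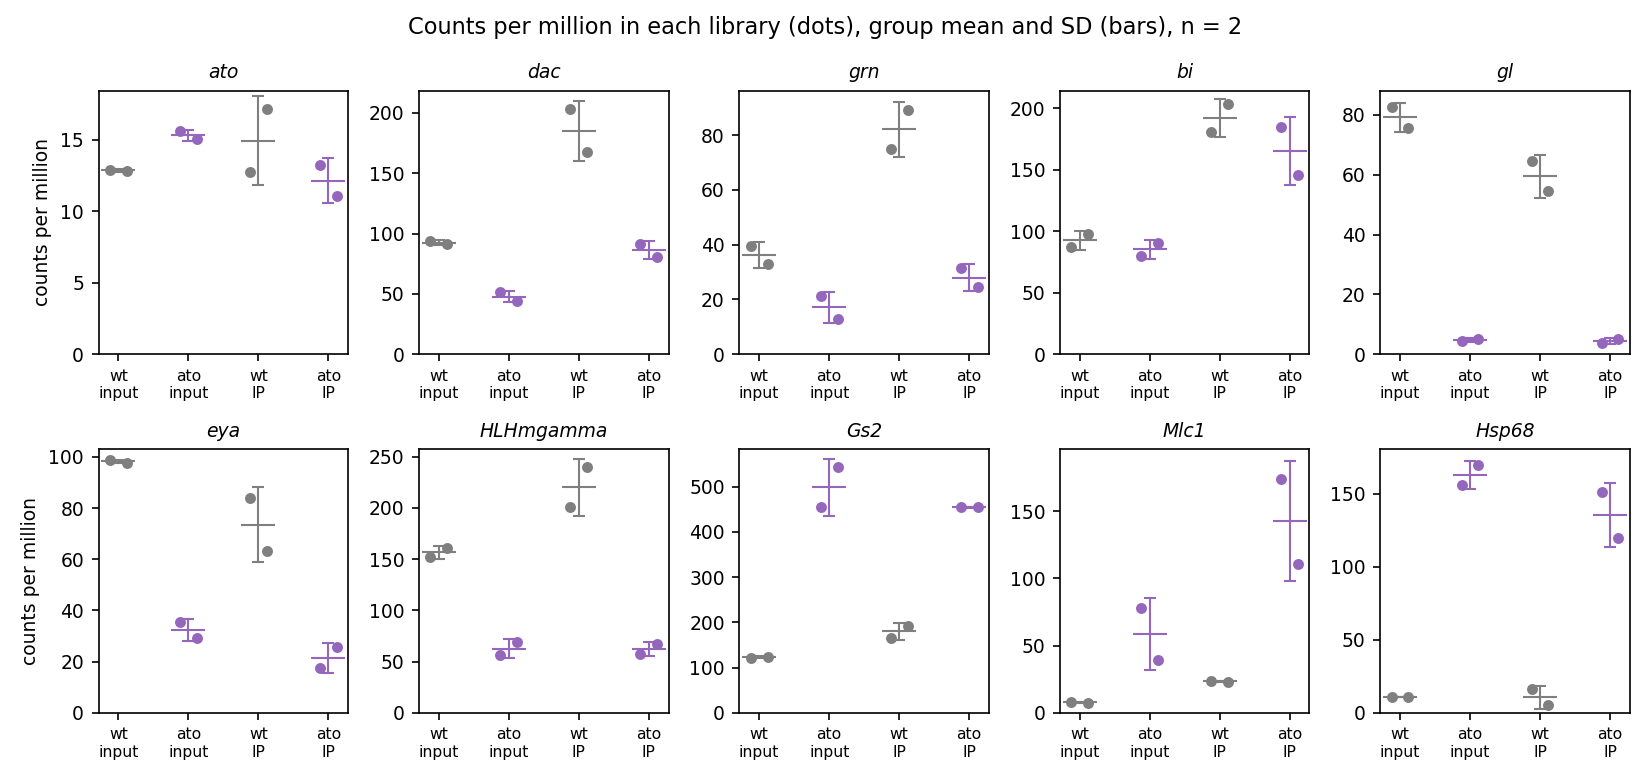
CPM (y axis) in each library (dots) of the 4 groups (x axis), with group mean and SD (bars, n = 2), for 10 genes. The gene ato sits at 12.1 to 15.3 CPM on average in all groups, dac is near 90 CPM in both wild-type input and ato IP (92.6 and 86.1) and highest in wild-type IP (185), and gl falls from 79.1 to 4.71 CPM in the inputs and from 59.5 to 4.45 in the IPs.

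The comparison of wild-type IP with wild-type input asks which transcripts were carried by the tagged ribosomes relative to the whole brain. Some genes of neurons and signalling were higher in the IP. The calcium channel gene cac was 7.23-fold higher (log2 2.85 ± 0.20, SE, n = 2 libraries per group, edgeR adjusted p = 2.79e-07), and the potassium channel gene Sh was 4.74-fold higher (2.25 ± 0.22, 3.94e-06). The bHLH gene tap rose from 78.3 to 567 CPM (2.86 ± 0.19, 1.79e-07), and the Notch receptor gene N was 3.29-fold higher (1.72 ± 0.20, 1.48e-05). Of the T4/T5 neuron identity factors, bi was 2.08-fold higher (1.05 ± 0.18, 0.000302), dac 2.00-fold (1.00 ± 0.18, 0.000433) and grn 2.26-fold (1.18 ± 0.25, 0.00161). Lower in the IP were Rpn7, which encodes a proteasome subunit, by 4.56-fold (-2.19 ± 0.18, 9.44e-07) and HP1c, which encodes a heterochromatin protein, by 4.48-fold (-2.16 ± 0.20, 2.49e-06). In all, 1773 of the 10224 genes were higher and 1882 lower in the IP, while DESeq2 size factors gave 1999 and 1619 and the DESeq2 Wald test 2127 and 1643, so which direction held more genes depended on the scaling.

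The 10 largest increases were those of snoRNA:Psi18S-1854b (54.3-fold, log2 5.76 ± 0.77), CG14609 (30.8-fold), the giant muscle protein gene bt (21.3-fold, 4.41 ± 0.37), CG5381 (18.1-fold), CG42621 (16.7-fold), CG13337 (16.3-fold), CG32655 (15.6-fold), CG15831 (14.6-fold), CG31781 (14.2-fold) and CG40155 (13.8-fold). The 10 largest decreases spanned a narrow range from CG17249 (4.59-fold, -2.20 ± 0.33) to CG4250 (4.26-fold, -2.09 ± 0.25), with Rpn7, HP1c, IFa, CG10341, CG9667, c12.1, CG2685 and CG31950 between them. The edgeR adjusted p-values of these 20 genes lay between 1.79e-07 and 0.00169.

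Neuronal lists moved together in wild type. Of the axon guidance and adhesion genes, 27 of 42 were higher and 0 lower (30 higher adjusted over the list alone), among them Ten-a (2.01 ± 0.21) and Sema-1a (1.38 ± 0.18). Camera gave this list an adjusted p = 1.38e-09, and adjusted p = 0.326 with an estimated correlation. Of the dpr, DIP, beat and side immunoglobulin genes, 26 of 54 were higher and 0 lower (26 adjusted over the list alone), with dpr8 at 1.71 ± 0.23 and dpr6 at 1.96 ± 0.29. Camera gave this family adjusted p = 1.29e-06, and adjusted p = 0.152 with an estimated correlation. The list of neuronal cell body and RNA-binding differentiation genes had 8 of 13 higher and 0 lower (9 adjusted over the list alone), led by Sh, the potassium channel gene Shab (2.59 ± 0.28) and the sodium channel gene para (2.71 ± 0.31). Its camera adjusted p = 2.2e-06, and adjusted p = 0.152 with an estimated correlation. Of the synaptic vesicle and active zone genes, 8 of 13 were higher, among them cac, Rim (2.23 ± 0.22) and Syt1 (1.45 ± 0.20), and 2 were lower, comt (-0.80) and Rop (-0.64). Adjusted over the list alone the counts were also 8 and 2, with camera adjusted p = 6.09e-05, and adjusted p = 0.326 with an estimated correlation. Neurotransmitter genes were higher in 4 of 12 and lower in 0, adjusted over the list alone too, with the choline acetyltransferase gene Cha (1.35 ± 0.22) and the tyrosine hydroxylase gene ple (2.61 ± 0.43) first. Their camera adjusted p = 0.0298, and adjusted p = 0.439 with an estimated correlation.

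Signalling lists also differed. Of the Notch pathway genes, 12 of 22 were higher and 0 lower (13 higher adjusted over the list alone), with N, kuz (1.66 ± 0.18) and Dl (1.16 ± 0.20) among them. The list had camera adjusted p = 0.000671, and adjusted p = 0.152 with an estimated correlation. Of the Dpp and Wnt pathway genes, 8 of 22 were higher, such as pan (1.21 ± 0.16) and fz2 (1.39 ± 0.22) and 1, the Smad gene Med (-0.90 ± 0.25), was lower. Camera gave them adjusted p = 0.0283, and adjusted p = 0.428 with an estimated correlation. Mushroom body markers were higher in 6 of 9, among them the cAMP genes dnc (1.08 ± 0.19) and rut (1.63 ± 0.29), with camera adjusted p = 0.0298, and adjusted p = 0.304 with an estimated correlation. Adjusted over the list alone, these last counts were again 8, 1 and 6. The Dpp and Wnt call was lost without wild-type input 2 (adjusted p = 0.0708) or wild-type IP 1 (0.199). The mushroom body call was lost without wild-type input 1 (0.0568), wild-type input 2 (0.058) or wild-type IP 1 (0.0779). With the length correction the calls of the Dpp and Wnt list (0.244), the neurotransmitter list (0.0913) and the mushroom body list (0.244) ended, as did that of the Dpp and Wnt list with no filter (0.0576).

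Most respiratory chain and cell cycle genes were lower in the IP. Of the nuclear-encoded respiratory chain genes, 39 of 61 were lower (40 adjusted over the list alone), such as Oscp (-1.48 ± 0.18) and CG7181 (-1.83 ± 0.26), and 1 was higher. Their camera adjusted p = 4.61e-12, and adjusted p = 0.428 with an estimated correlation. Of the cell cycle genes, 23 of 36 were lower, among them the Aurora B kinase gene ial (-1.54 ± 0.17) and borr (-1.54 ± 0.19), and 2 were higher, the phosphatase gene stg (0.72) and the cell cycle inhibitor gene dap (1.25 ± 0.19). Adjusted over the list alone 23 were lower and 3 higher, with camera adjusted p = 2.2e-06, and adjusted p = 0.304 with an estimated correlation. Cytosolic ribosomal protein genes were higher in 28 of 87 and lower in 3 (the same counts adjusted over the list alone), with RpS29 at 1.28 ± 0.21 and RpLP0 at 0.91 ± 0.16. Camera gave adjusted p = 0.00137, and adjusted p = 0.746 with an estimated correlation. The preset call of this list was lost without wild-type input 2 (0.0597) or wild-type IP 2 (0.733). Small nuclear and nucleolar RNA genes were higher in 12 of 53 and lower in 0 (8 higher adjusted over the list alone), with a median log2 of 1.75, camera adjusted p = 6.09e-05, and adjusted p = 0.152 with an estimated correlation. The dosage compensation RNAs roX1 (1.56 ± 0.16, edgeR adjusted p = 4.65e-06) and roX2 (1.81 ± 0.22, 1.84e-05) were both higher.

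Markers of other cell types, such as muscle and glia, were present in the IP as well. All 9 muscle markers were higher in the wild-type IP than in its input (9 also adjusted over the list alone), with Mhc at 10.6-fold (3.40 ± 0.46) and sls at 6.58-fold (2.72 ± 0.31). The list's camera adjusted p = 1.38e-09, and adjusted p = 0.304 with an estimated correlation. Glial markers (2 of 13 higher, 2 lower, median 0.17), photoreceptor and eye disc markers (1 of 10 higher and 0 adjusted over the list alone, median -0.05, mean 0.27), hemocyte markers (2 of 10 higher, Hml and crq, median 0.56) and fat body markers (0 of 6, median 0.81) had camera adjusted p = 0.895, 0.895, 0.227 and 0.425. The glial counts rest on the ensheathing gene wrapper (-1.42 ± 0.25, edgeR adjusted p = 0.000366), Gs2, Gli and loco. The calls of these last 3 were lost without wild-type input 1 (0.138, 0.144 and 0.115), wild-type input 2 (0.108, 0.0549 and 0.0611) or wild-type IP 2 (0.0792, 0.0894 and 0.199). The Hml call was lost without wild-type input 2 (0.0531) or wild-type IP 1 (0.5), and the crq call without wild-type input 1 (0.0755), wild-type input 2 (0.273) or wild-type IP 2 (0.126). The single photoreceptor call, boss, was lost without wild-type input 1 (0.112), wild-type input 2 (0.0942) or wild-type IP 2 (0.117). With 1 run per library the calls of boss (0.102) and crq (0.0867) ended, and with the length correction that of Hml (0.221).

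The other lists were not called by camera in wild type. The T4/T5 neuron identity factors had 3 of 8 higher and 0 lower (adjusted p = 0.0878), with ato, acj6, SoxN, Sox102F and AP-2 not passing. The EGF receptor pathway had 5 of 16 higher (0.0878), with kek1 at 1.04 ± 0.17. Heat shock genes had 4 of 10 lower, among them Hsp27 (-1.05 ± 0.19), and 1 higher (0.0878). Neuroblast genes had 8 of 22 higher and 3 lower (0.227), with klu at 1.58 ± 0.17. The temporal factors of the distal inner proliferation center had D lower (-1.38 ± 0.17), dpn lower and dac higher (0.378). Lists with adjusted p between 0.266 and 0.895 and few calls were the neuroepithelial polarity genes (4 higher and 1 lower of 10), the proneural genes (1 and 1 of 10, median -0.04 but mean 0.19), the Atonal targets known from sense organs (1 and 0 of 6), and the lamina (3 and 0 of 8), medulla (2 and 1 of 12), trachea (1 and 0 of 4), ring gland (0 of 7) and glue (0 of 6) lists. In that range lay also the apoptosis genes (2 and 3 of 10, with the caspase gene Ice at -1.77 ± 0.18) and antimicrobial peptide genes (1 and 1 of 7, median -0.67 but mean 0.44). Adjusted over the list alone the counts of these lists differed only for the temporal factors (3 lower) and the trachea list (2 higher). The call of dpn was lost without wild-type input 1 (0.0777), wild-type input 2 (0.109) or wild-type IP 2 (0.0514), or with 1 run per library (0.149).

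Long genes were favoured in the IP. Across genes, log2 IP over input rose with exon length (Spearman 0.175) and fell with abundance (Spearman -0.45), and in ato the values were 0.285 and -0.372. Between genotypes the trend with length went the other way, at -0.272 in the inputs and -0.16 in the IPs. By mean CPM, the lowest of 6 bins of genes (0.339 to 2.52 CPM) had a median of 2.23 in wild type and 1.59 in ato. By length, the median in wild type was 0.47 in the longest of 6 length bins and between -0.16 and 0.08 in the other bins. Leaving out either wild-type input lowered the counts of genes called higher and lower in wild type, with fewer libraries left to the test. Of the 113 called genes taken by rank or list in this comparison, 18 lost their call when a library was left out.

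**Figure D2:**
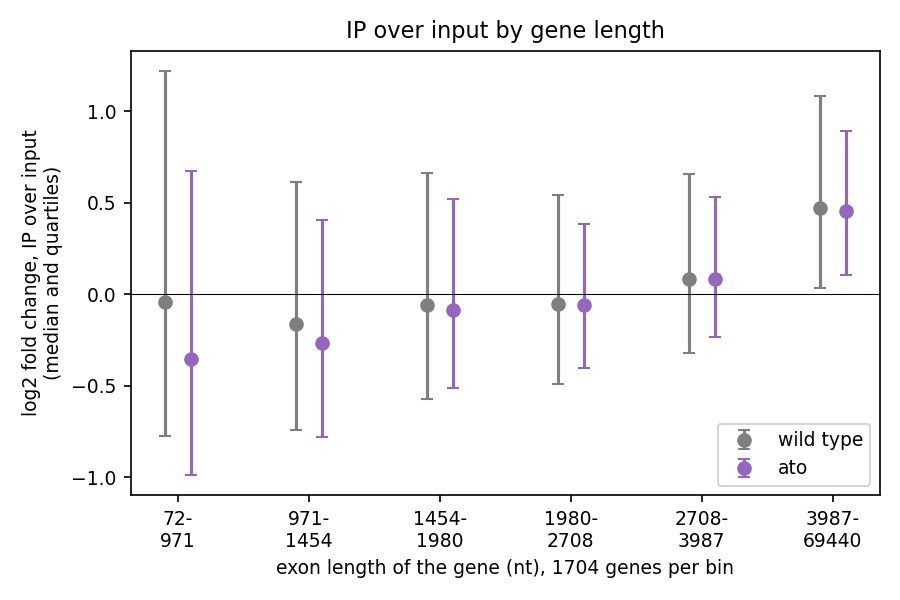
Median (points) and quartiles (bars) of the log2 ratio of IP over input (y axis) for 6 bins of 1704 genes by exon length in nucleotides (x axis), in wild type (grey) and ato (purple). The longest bin has medians of 0.47 and 0.45, and the shortest has -0.04 and -0.35.

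The same comparison in ato asks whether the tagged ribosomes carried the same transcripts without ato function. The genes cac, Sh and tap were again higher in the IP: cac was 4.33-fold higher (log2 2.12 ± 0.20, SE, n = 2 libraries per group, edgeR adjusted p = 7.79e-06), Sh 3.54-fold (1.82 ± 0.22, 3.08e-05) and tap 4.71-fold (2.24 ± 0.19, 4.15e-06). Of the T4/T5 neuron identity factors, bi was 1.94-fold higher (0.95 ± 0.18, 0.000897) and dac was higher too (0.85 ± 0.18, 0.00236). The value of grn was 0.72 ± 0.26 (0.0477), a call that was lost without ato input 2 (0.347) or ato IP 1 (0.273), with limma-voom (0.0589), with the length correction (0.164), with only the groups compared (0.0782) and with 1 run per library (0.368). A gene of the respiratory chain, CG12203, which encodes a subunit of complex I, was 3.62-fold lower (-1.85 ± 0.19, 9.6e-06). In all, 1217 genes were higher and 1669 lower.

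The largest increases in ato were those of CG33286, at least 63.9-fold, CG32228 (34.5-fold, 5.11 ± 0.91), snoRNA:Psi18S-1854b (21.6-fold, 4.43 ± 0.74), snoRNA:Psi18S-1854c (4.09 ± 0.88) and the mucin gene Muc14A (14.9-fold, 3.90 ± 0.61). The largest decreases were those of Peritrophin-15b (7.05-fold), CG6196 (5.86-fold, -2.55 ± 0.51), CG5084 (5.56-fold), CG6769 (5.15-fold, -2.37 ± 0.30) and CG31950 (5.05-fold, -2.34 ± 0.37). Adjusted p-values of these genes in edgeR lay between 4.59e-05 and 0.0118. The call of snoRNA:Psi18S-1854c was lost without ato IP 1 (0.293). That of Peritrophin-15b was lost without ato input 1 (0.0744) or ato IP 1 (0.0676), and that of CG5084 without ato input 1 (0.167) or ato IP 2 (0.0628). The DESeq2 Wald test called neither of them (0.175 and 0.131).

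In ato, 10 lists were higher and 2 lower in the IP by camera, and 0 of these 12 held with an estimated correlation. Axon guidance genes were higher in 24 of 42 (27 adjusted over the list alone), with Sema-1a at 1.31 ± 0.18 (camera adjusted p = 1.32e-08, and adjusted p = 0.311 with an estimated correlation). The dpr, DIP, beat and side genes were higher in 16 of 54 (17 adjusted over the list alone), with dpr6 at 1.86 ± 0.29 (0.000128, and adjusted p = 0.24 with an estimated correlation). Neuronal cell body genes were higher in 7 of 13 (7 adjusted over the list alone), with para at 2.08 ± 0.30 (7.22e-05, and adjusted p = 0.24 with an estimated correlation). Synaptic genes were higher in 7 of 13, with Rim at 1.64 ± 0.22 (0.00163, and adjusted p = 0.356 with an estimated correlation), and 8 were higher and 2 lower adjusted over the list alone. Notch pathway genes were higher in 8 of 22 (9 adjusted over the list alone), with kuz at 1.06 ± 0.18 (0.00715, and adjusted p = 0.24 with an estimated correlation). The Dpp and Wnt list had 8 of 22 higher and 1 lower (10 and 1 adjusted over the list alone), with pan at 1.09 ± 0.16 (0.00373, and adjusted p = 0.311 with an estimated correlation). Neurotransmitter genes were higher in 3 of 12 (4 adjusted over the list alone), with ple at 2.30 ± 0.42 (0.0186, and adjusted p = 0.362 with an estimated correlation). That call was lost without ato input 1 (0.0967) or ato IP 2 (0.0962).

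All 9 muscle markers were again higher in the IP (9 adjusted over the list alone), with sls at 10.7-fold (3.42 ± 0.32) and bt at 11.9-fold (3.58 ± 0.34). Their camera adjusted p = 4.11e-08, and adjusted p = 0.311 with an estimated correlation. Small nuclear and nucleolar RNA genes were higher in 9 of 53 (8 adjusted over the list alone, camera adjusted p = 1.91e-05, and adjusted p = 0.24 with an estimated correlation). Respiratory chain genes were lower in 43 of 61 (46 adjusted over the list alone), with Oscp at -1.53 ± 0.18 (8e-19, and adjusted p = 0.311 with an estimated correlation). Cell cycle genes were lower in 17 of 36 and higher in 2 (18 and 2 adjusted over the list alone), with Bub3 at -1.22 ± 0.17 (0.000683, and adjusted p = 0.311 with an estimated correlation). Salivary gland glue genes were higher in 2 of 6 (2 adjusted over the list alone), with a median of 3.25, or 2.71 with the member at 0 placed at its bound (0.0435, and adjusted p = 0.311 with an estimated correlation). Sgs7, 1 of these, had a count ratio of 13.2 (3.28 to 115), and its call was lost without ato input 2 (0.0781) or ato IP 1 (0.0539), with limma-voom (0.119) and with 1 run per library (0.083). The glue call was lost without ato input 1 (0.0967) or ato IP 2 (0.051), with DESeq2 size factors (0.0586), with the stricter filter (0.0503), with 1 run per library (0.273) and with counts halved (0.13). The ribosomal protein genes (6 higher and 5 lower of 87, 5 and 3 adjusted over the list alone) had adjusted p = 0.248. The T4/T5 neuron identity factors (4 of 8 higher, adjusted over the list alone too, of which Sox102F was lost without ato input 1, 0.282, or ato IP 1, 0.275, with library totals, 0.0521, and with only the groups compared, 0.0574) had 0.104, glial markers (2 higher and 3 lower of 13) 0.961 and photoreceptor markers (3 of 10 higher) 0.168. The 20 lists not called had adjusted p = 0.0634 or more, and median and mean differed in sign for hemocyte markers (0.05 and -0.02) and apoptosis genes (0.08 and -0.13). For proneural genes (median -0.34, mean -0.08) and lamina markers (-0.21 and -0.02) both were negative while the test pointed up, and for antimicrobial peptide genes (0.13 and 0.04) both were positive while it pointed down.

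IP-over-input calls overlapped widely between genotypes. Of the genes called, 954 were higher in both, where independent lists would share 211.0, and 1354 were lower in both (307.2), with 0 called in opposite directions (289.4 and 224.0). The comparisons share no libraries. Fold changes correlated across genes at 0.742 (Pearson) and 0.814 (Spearman), where genes are not independent replicates. In ato the number of genes higher fell to 684 without ato input 1 and to 617 without ato IP 1, and the number lower to 1022 and 1072. Of the 105 called genes taken by rank or list in ato, 39 lost their call when a library was left out. The balance depended on the scaling in ato too: DESeq2 size factors moved the median of all genes by 0.107 and gave 1460 higher and 1350 lower. With the length correction the calls of the Dpp and Wnt (0.161), synaptic (0.152) and neurotransmitter (0.0844) lists ended.

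The comparison of ato IP with wild-type IP addresses the question in the series title, how ribosome-bound RNA differs without ato function. Some genes of the lineage and of the eye were lower in ato. Of the T4/T5 neuron identity factors, grn, a GATA factor gene, was 2.94-fold lower (log2 -1.55 ± 0.25, SE, n = 2 libraries per group, edgeR adjusted p = 0.00128) and dac, a nuclear factor gene, 2.15-fold lower (-1.11 ± 0.18, 0.00125), while bi stood at -0.22 ± 0.18 (0.601). The eye transcription factor gene gl was 13.4-fold lower (-3.74 ± 0.27, 3.83e-07), and eya was 3.42-fold lower (-1.77 ± 0.23, 0.000146). The Notch target gene HLHmgamma, now E(spl)mgamma-HLH, was 3.52-fold lower (-1.82 ± 0.18, 1.6e-05). Some stress, glial and muscle genes were higher: Hsp68 rose 12.5-fold (3.65 ± 0.33, 7.11e-06), the glutamine synthetase gene Gs2 2.53-fold (1.34 ± 0.16, 7.63e-05) and the myosin light chain gene Mlc1 6.13-fold (2.62 ± 0.29, 3e-05). In all, 288 genes were higher and 192 lower in ato.

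The 10 largest increases were those of the heat shock cognate gene Hsc70-2 (386-fold, 8.59 ± 0.54), the serine protease genes yip7 (97.7-fold) and Jon65Aiv (57.9-fold), CG7715 (47.9-fold), CG17134 (47.0-fold), the glutathione S-transferase gene GstD5 (44.1-fold, 5.46 ± 0.54), CG31157 (41.7-fold, 5.38 ± 0.65), Hsp70Ba (36.8-fold), CG14265 (27.7-fold) and CG15213 (22.2-fold). The 10 largest decreases were those of CG6912 (26.0-fold, -4.70 ± 0.35), the glue protein gene Sgs7 (21.4-fold, -4.42 ± 0.49), CG3984 (18.1-fold), CG30101 (13.7-fold), gl, CG5653 (12.3-fold), CG9150 (11.7-fold), CG32572 (10.3-fold), the rhomboid protease gene ru (9.50-fold, -3.25 ± 0.34) and the villin gene qua (8.72-fold). Their edgeR adjusted p-values lay between 7.43e-08 and 0.0154. With limma-voom yip7 (0.263), Jon65Aiv (0.138), CG7715 (0.0562), CG17134 (0.301) and CG14265 (0.0771) were not called. The DESeq2 Wald test did not call Jon65Aiv (0.0612), CG17134 (0.12) or CG15213 (0.2). CG17134 was lost without wild-type IP 2 (0.0532) or ato IP 1 (0.223), CG14265 without ato IP 1 (0.056), CG15213 without ato IP 2 (0.0788), and CG14265 and CG32572 with 1 run per library (0.0532 and 0.0996).

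Lineage and signalling lists were lower in ato IPs, and 0 of the 18 lists called held with an estimated correlation. Of the Notch pathway genes, 8 of 22 were lower and 0 higher (14 lower adjusted over the list alone), among them HLHmgamma, malpha (-1.35 ± 0.22) and HLHmdelta (-2.16 ± 0.36). The camera adjusted p of the pathway was 3.5e-12, and adjusted p = 0.0524 with an estimated correlation. The T4/T5 neuron identity factors had 2 of 8 lower (4 adjusted over the list alone), dac and grn, with camera adjusted p = 0.000208, and adjusted p = 0.14 with an estimated correlation. The temporal factors had dac and tll lower (2 of 6, also adjusted over the list alone), with camera adjusted p = 0.0211, and adjusted p = 0.181 with an estimated correlation. Of the EGF receptor pathway genes, aop (-0.96 ± 0.17) and spi (-0.89 ± 0.16) were lower (2 of 16, and 3 adjusted over the list alone), with camera adjusted p = 3.9e-05, and adjusted p = 0.106 with an estimated correlation. Axon guidance genes had 2 of 42 lower, hbs and ena (6 adjusted over the list alone, camera adjusted p = 3.17e-05, and adjusted p = 0.358 with an estimated correlation). The Dpp and Wnt list had 1 of 22 lower, nkd (3 adjusted over the list alone, 0.0126, and adjusted p = 0.33 with an estimated correlation). Photoreceptor markers had 3 of 10 lower (6 adjusted over the list alone), gl, eya and ro, with camera adjusted p = 6.04e-09, and adjusted p = 0.0761 with an estimated correlation. Lamina markers had 4 of 8 lower (5 adjusted over the list alone), eya, dac, sim and tll, with camera adjusted p = 3.22e-07, and adjusted p = 0.0836 with an estimated correlation.

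Several of these gene calls were lost when a library was left out, which also leaves fewer libraries to the test. Without ato IP 2 the calls of aop (0.0606), ena (0.257), hbs (0.11), nkd (0.501), sim (0.341) and tll (0.256) were lost, and without ato IP 1 those of spi (0.057), hbs (0.104), ro (0.0843) and tll (0.153). Without wild-type IP 1 the calls of hbs (0.0541), nkd (0.0875) and sim (0.156) were lost, and without wild-type IP 2 those of nkd (0.0984), ro (0.0862), sim (0.054) and tll (0.175). Other settings ended calls too: DESeq2 size factors those of tll (0.0571) and nkd (0.0634), library totals (0.0686), the stricter filter (0.0507) and the length correction (0.0678) that of nkd, and limma-voom those of tll (0.071) and ro (0.0539). With only the groups compared tll (0.0937), nkd (0.125), sim (0.0619) and ena (0.0533) were lost, and with 1 run per library tll (0.478), sim (0.207) and ro (0.169). Of the 64 called genes taken by rank or list between IPs, 31 lost their call when a library was left out. The Dpp and Wnt list was lost without wild-type IP 1 (0.182) or ato IP 2 (0.0574) and with the length correction (0.166).

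Stress, glial and muscle lists were higher in ato IPs. Of the heat shock genes, 4 of 10 were higher, Hsp68, Hsp70Ba, Hsp70Bc (4.06 ± 0.56) and Hsp26 (1.30 ± 0.24), and Hsp67Bc was lower (6 and 1 adjusted over the list alone). For this list the camera adjusted p = 5.75e-09, and adjusted p = 0.0524 with an estimated correlation. Muscle markers were higher in 7 of 9 (8 adjusted over the list alone), such as Mlc2 (2.76 ± 0.32) and Act57B (3.47-fold), with camera adjusted p = 1.63e-13, and adjusted p = 0.14 with an estimated correlation. Glial markers were higher in 5 of 13 (7 higher and 3 lower adjusted over the list alone), with Gs2 and the GABA transporter gene CG1732, now Gat (1.72 ± 0.29), first. Their camera adjusted p = 0.00491, and adjusted p = 0.14 with an estimated correlation. Fat body markers had 0 of 6 called (3 adjusted over the list alone) and a median of 1.32, with camera adjusted p = 0.00262, and adjusted p = 0.38 with an estimated correlation. Hemocyte markers were higher in 3 of 10, adjusted over the list alone too, with Hml at 1.56 ± 0.36 (camera adjusted p = 0.041, and adjusted p = 0.417 with an estimated correlation). Neurotransmitter genes were higher in 2 of 12, the tryptophan hydroxylase gene Trh (1.64 ± 0.33) and Gad1 (1.10 ± 0.25), with 3 adjusted over the list alone (0.0115, and adjusted p = 0.353 with an estimated correlation). Without ato IP 2 the calls of Trh (0.119), Gad1 (0.193), the neurotransmitter list (0.0614) and the hemocyte list (0.0665) were lost. Without wild-type IP 2 those of Hml (0.0526), the hemocyte list (0.262) and the fat body list (0.126) were lost, and without ato IP 1 those of Hml (0.0748) and the hemocyte list (0.0641).

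The remaining lists called in the IPs had at most 1 called member each. Glue genes had 1 of 6 lower, Sgs7 (2 adjusted over the list alone), with a median of -2.39 (camera adjusted p = 0.000208, and adjusted p = 0.14 with an estimated correlation). Respiratory chain genes had 0 of 61 called, adjusted over the list alone too, with a median of 0.19 (0.0115, and adjusted p = 0.721 with an estimated correlation). Medulla markers had tll lower (1 of 12, and 3 adjusted over the list alone, 0.0297, and adjusted p = 0.181 with an estimated correlation). Of the apoptosis genes only W, also named hid, was called lower (1 of 10 and 2 adjusted over the list alone, 0.041, and adjusted p = 0.436 with an estimated correlation). The call of W was lost without wild-type IP 2 (0.0616) or ato IP 2 (0.187). That of the respiratory list was lost without wild-type IP 1 (0.71, median -0.00), and that of the apoptosis list without wild-type IP 2 (0.226) or ato IP 1 (0.196). With the length correction the respiratory (0.554) and medulla (0.0845) lists were not called, with only the groups compared the medulla (0.0514) and apoptosis (0.0742) lists were not, and neither of these was with 1 run per library (0.0938 and 0.119). The apoptosis call was also lost with the stricter filter (0.0644) and with counts halved (0.0544).

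The 14 lists not called between IPs had adjusted p = 0.0529 or more. Among the Atonal targets known from sense organs, dap was lower (-1.06 ± 0.19, edgeR adjusted p = 0.00229) and the other 5 were not called. Of the synaptic genes 0 of 13 and of the dpr, DIP, beat and side genes 0 of 54 were called, adjusted over the list alone too, with medians of -0.00 and -0.10. Proneural genes had sc lower (-1.16 ± 0.23, 0.00545), a call lost without ato IP 2 (0.119). Neuroblast genes had 1 higher, Imp (lost without wild-type IP 1, 0.0978, or ato IP 1, 0.0648), and 3 lower of 22 (4 and 5 adjusted over the list alone), and cell cycle genes 2 higher, ncd and ial, and 1 lower, dap, of 36. The 3 lower neuroblast genes, scrt, grh and klu, were lost without ato IP 2 (0.2, 0.486 and 0.248), with only the groups compared (0.0639, 0.114 and 0.123) and with 1 run per library (0.136, 0.204 and 0.153), and grh and klu with DESeq2 size factors (0.0546 and 0.0588) and library totals (0.0615 and 0.0504). The calls of ncd and ial were lost without ato IP 1 (0.0783 and 0.0993) or ato IP 2 (0.128 and 0.145). Median and mean differed in sign for the synaptic (mean 0.07) and mushroom body lists (-0.26 and 0.09), and for ring gland markers both were below 0 (-0.03 and -0.06) while the test pointed up. Without ato IP 2 the gene counts between IPs fell to 179 higher and 55 lower, and with only the groups compared 114 were lower. With no low-count filter 452 were higher and 356 lower.

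Whole-brain RNA asks which genotype differences were present before the pull-down. The eye genes gl and eya were lower in ato inputs by 16.7-fold (log2 -4.06 ± 0.26, SE, n = 2 libraries per group, edgeR adjusted p = 9.3e-08) and 3.04-fold (-1.61 ± 0.23, 0.000236), and dac was 1.94-fold lower (-0.95 ± 0.18, 0.00306). HLHmgamma was lower (-1.32 ± 0.18, 0.000193). The glial gene Gs2 was 4.06-fold higher (2.02 ± 0.17, 1.93e-06), Mlc1 7.63-fold higher (2.93 ± 0.31, 1.32e-05) and Hsp68 14.9-fold higher (3.89 ± 0.33, 1.93e-06). In all, 474 genes were higher and 239 lower. The largest increases were those of yip7, at least 462-fold, Hsp70Ba, at least 119-fold, Jon25Bi, at least 85.2-fold, Hsc70-2 (375-fold, 8.55 ± 0.51) and Jon65Aiv (178-fold, 7.47 ± 0.99). The largest decreases were those of CG3984, at least 84.2-fold, Sgs7, with a count ratio of 179 (49.2 to 1481), qua (30.5-fold, -4.93 ± 0.51), CG6912 (28.7-fold, -4.84 ± 0.38) and CG9150 (18.9-fold, -4.24 ± 0.36). With limma-voom yip7 (0.0692) and Jon65Aiv (0.0612) were not called. The adjusted p-values of these 10 genes in edgeR lay between 3.21e-08 and 0.00121.

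Tissue markers differed in the inputs. Photoreceptor markers were lower in 6 of 10 (6 adjusted over the list alone) and had a median of -2.29, with ro at -3.42 ± 0.52. Their camera adjusted p = 4.08e-13, and adjusted p = 0.0586 with an estimated correlation. Muscle markers were higher in 8 of 9, such as Act57B (2.62 ± 0.30), while sls stood at -0.69 ± 0.30 (edgeR adjusted p = 0.2). Adjusted over the list alone 8 were higher and 1 lower, with camera adjusted p = 1.33e-16, and adjusted p = 0.145 with an estimated correlation. Glue genes were lower in 4 of 6 (5 adjusted over the list alone), with a median of -4.98, or -3.93 with members at 0 placed at their bound (4.11e-07, and adjusted p = 0.134 with an estimated correlation). Heat shock genes were higher in 4 of 10 and lower in 1, Hsp67Bc (the same counts adjusted over the list alone), with Hsp70Bc at 4.76 ± 0.60 (4.11e-07, and adjusted p = 0.0586 with an estimated correlation). Glial markers were higher in 5 of 13 and lower in 1, loco (5 and 4 adjusted over the list alone, 0.00957, and adjusted p = 0.162 with an estimated correlation). Hemocyte markers were higher in 4 of 10 (5 adjusted over the list alone), with Hml at 2.23 ± 0.37 (0.000785, and adjusted p = 0.234 with an estimated correlation). Fat body markers were higher in 3 of 6 (4 adjusted over the list alone, median 1.56, 0.00103, and adjusted p = 0.321 with an estimated correlation). These 3, Lsp1alpha, Lsp1beta and Lsp1gamma, were lost without wild-type input 2 (0.151, 0.0804 and 0.248), and without ato input 2 (Lsp1alpha, 0.0608) or ato input 1 (Lsp1beta, 0.0894, and Lsp1gamma, 0.283). With 1 run per library Lsp1alpha (0.116) and Lsp1gamma (0.0594) were lost too, and with the DESeq2 Wald test Lsp1beta (0.186).

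Some lineage and signalling genes were lower in the inputs too. The T4/T5 neuron identity factors had 3 of 8 lower (4 adjusted over the list alone), dac, Sox102F (-1.07 ± 0.23) and grn (-1.09 ± 0.26), with camera adjusted p = 0.00361, and adjusted p = 0.234 with an estimated correlation. The call of Sox102F was lost without ato input 1 (0.0867) and that of grn without wild-type input 1 (0.113) or ato input 2 (0.113). The temporal factors had 2 of 6 lower, dac and tll, adjusted over the list alone too (0.0249, and adjusted p = 0.234 with an estimated correlation). Notch pathway genes were lower in 7 of 22 (9 adjusted over the list alone), with malpha at -1.12 ± 0.23 (1.03e-06, and adjusted p = 0.0586 with an estimated correlation). The EGF receptor pathway had 3 of 16 lower, adjusted over the list alone too, with aop at -1.05 ± 0.17 (0.00038, and adjusted p = 0.134 with an estimated correlation). Lamina markers had 3 of 8 lower, eya, dac and tll, adjusted over the list alone too (0.00117, and adjusted p = 0.162 with an estimated correlation). The call of tll was lost without wild-type input 1 (0.0711), wild-type input 2 (0.211) or ato input 2 (0.115), or with 1 run per library (0.0722). The temporal factor list was lost without ato input 2 (0.0554), with 1 run per library (0.11) and with the length correction (0.0609).

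The other lists called between inputs had few called members. Ribosomal protein genes had 2 of 87 higher (1 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 4.11e-07, and adjusted p = 0.529 with an estimated correlation). Respiratory chain genes had 3 of 61 higher (0 adjusted over the list alone, 0.000191, and adjusted p = 0.529 with an estimated correlation). Synaptic genes had 2 of 13 higher (4 adjusted over the list alone, 0.022, and adjusted p = 0.422 with an estimated correlation), and neurotransmitter genes 2 of 12 (3 adjusted over the list alone, 0.0147, and adjusted p = 0.333 with an estimated correlation). Lower were the Dpp and Wnt list (0 of 22, 0.00459, and adjusted p = 0.261 with an estimated correlation), the axon guidance list (3 of 42, 0.0157, and adjusted p = 0.529 with an estimated correlation) and the neuroepithelial polarity list (0 of 10, 0.0448, and adjusted p = 0.394 with an estimated correlation), with the same counts adjusted over the list alone. Apoptosis genes had 1 of 10 lower, Ice (5 lower and 1 higher adjusted over the list alone, 0.0239, and adjusted p = 0.393 with an estimated correlation). Without ato input 2 the synaptic (0.334), neurotransmitter (0.227) and apoptosis (0.0891) lists were lost, without wild-type input 1 the polarity (0.0949) and synaptic (0.115) lists, and without ato input 1 the polarity (0.0983) and respiratory (0.146) lists. The call of Ice was lost without any 1 of the 4 inputs (0.0532 to 0.23) and with 1 run per library (0.116). Short genes as a whole lay higher in ato inputs, with medians from 0.30 in the shortest of 6 length bins to -0.19 in the longest. With the length correction the Dpp and Wnt (0.182), axon guidance (0.902, median 0.03), polarity (0.445), ribosomal (0.445) and respiratory (0.78) calls ended. With 1 run per library the polarity (0.11) and apoptosis (0.0584) calls ended, and the polarity call did so with the stricter filter (0.0741), with only the groups compared (0.0602) and with counts halved (0.0609).

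The 12 lists not called between inputs had adjusted p = 0.0565 or more. In the Atonal targets list (0.0565) sens was lower (-3.19 ± 0.75, edgeR adjusted p = 0.014), a call lost without ato input 1 (0.0624) and with 1 run per library (0.113). Among neuroblast genes Imp was higher (0.99 ± 0.17, 0.0012), and 3 were higher and 3 lower of 22 (4 and 7 adjusted over the list alone). Median and mean differed in sign for cell cycle genes (0.04 and -0.06) and small nuclear and nucleolar RNA genes (-0.01 and 0.13). The gene counts between inputs fell without wild-type input 1 to 296 higher and 105 lower, without wild-type input 2 to 239 and 82, and without ato input 1 to 312 and 130. With no low-count filter 390 were lower, and with 1 run per library 157. Of the 76 called genes taken by rank or list between inputs, 47 lost their call when a library was left out.

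Genotype differences in the IPs overlapped in part with those in the inputs. Of the 713 genes called between inputs, 333 were also called between IPs, 380 were called between inputs only and 147 between IPs only. Of these shared genes, 225 were higher in both, where independent lists would share 13.4, and 108 were lower in both (4.49), with 0 called in opposite directions (6.73 and 8.90). The comparisons share no libraries, but IP and input came from the same homogenates. Fold changes of the pair correlated across genes at 0.552 (Pearson) and 0.504 (Spearman), where genes are not independent replicates, and 701 (98.3%) of the genes called between inputs had the same direction in the IPs. The mean log2 CPM of muscle markers was 3.21 and 3.07 in wild-type inputs, 5.61 and 4.82 in ato inputs, 5.55 and 5.42 in wild-type IPs, and 7.51 and 6.53 in ato IPs.

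**Figure D3:**
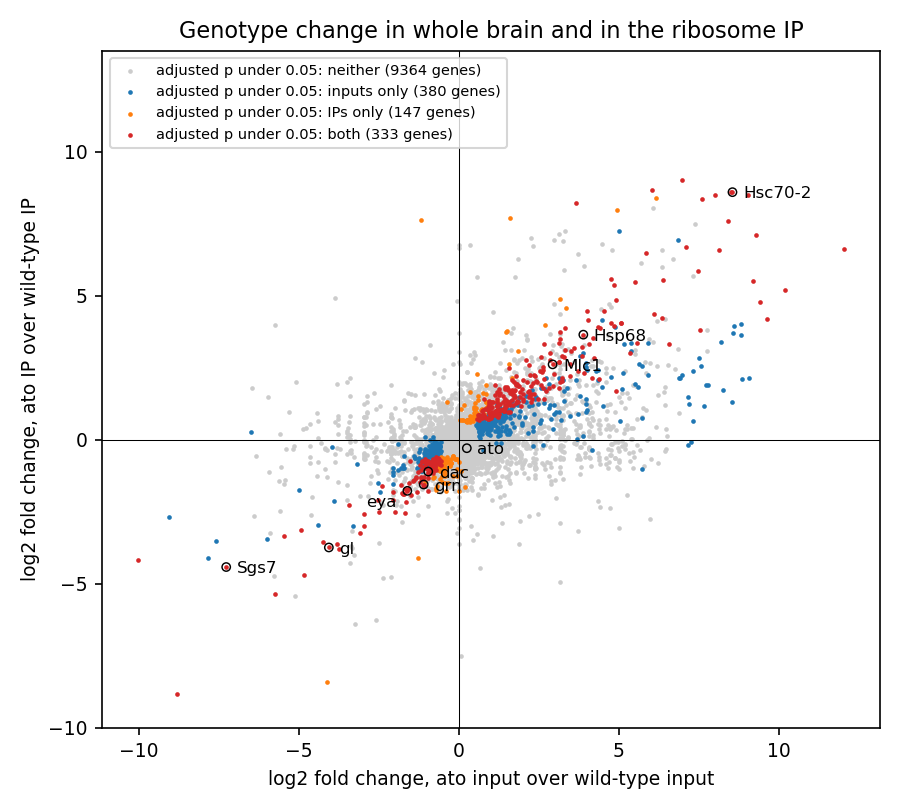
Log2 fold change of each of 10224 genes from wild type to ato in the inputs (x axis) and in the IPs (y axis), coloured by whether the adjusted p is below 0.05 in neither, inputs only (380), IPs only (147) or both (333), with 9 genes named. The fitted folds of genes with a group at 0 depend on the prior count, and gl, eya, dac and grn lie low while Mlc1, Hsp68 and Hsc70-2 lie high on both axes.

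The last comparison asks whether the enrichment in the IP differed between genotypes. With edgeR 0 genes were called in either direction, with a smallest adjusted p of 0.307 and 436 genes at an unadjusted p below 0.05 (113 higher in ato, 323 lower). Limma-voom called 0 (367 at an unadjusted p below 0.05), and the DESeq2 Wald test called 1, the amino acid transporter gene CG7888 (adjusted p = 0.0312). The smallest unadjusted p-values on the lower side were those of CG7888 (log2 -3.23 ± 0.57, SE), CG9657 (-2.27 ± 0.50), sda (-1.33 ± 0.32), Proc-R (-1.94 ± 0.49) and CG6947 (-6.94 ± 1.76). On the higher side stood GstD3 (1.29 ± 0.30), CG3984 (5.85 ± 1.51), CG4328 (1.68 ± 0.47), CG10341 (0.99 ± 0.28) and CG11961 (0.90 ± 0.26), all at adjusted p = 0.991. The fitted values of CG3984 and CG6947, each with a group at 0, depend on the prior count. With the homogenate as a block 10 genes were called lower: CG7888 (0.000908), CG9657 (0.0143), sda (0.0341), CG6947 (0.000438), CG9021, jp, Mmp1, Phk-3, CG9192 and Tsf1, the last 6 of which were named after their values were seen. Without a low-count filter 9 were called lower, without wild-type input 1 there were 3 and without wild-type IP 2 there were 2.

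Among lists, 8 were called in this comparison by camera with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.687), and 0 members passed in any list. The preset adjusted p was 0.00398 for cell cycle genes, 0.0104 for photoreceptor markers, 0.000721 for glue genes, 0.0149 for muscle markers, 0.0197 for the dpr, DIP, beat and side genes, 0.000144 for ribosomal protein genes, 0.0486 for synaptic genes and 0.0495 for neuronal cell body genes, which were not called with the homogenate as a block (0.051). Higher in ato were the cell cycle genes (median 0.149), the photoreceptor markers (0.824) and the glue genes (2.69). Lower were the muscle markers (-0.825), the dpr, DIP, beat and side genes (-0.374), the ribosomal protein genes (-0.29), the synaptic genes (-0.229) and the neuronal cell body genes (-0.2). For example, Sgs7 was carried in the ato IP over its input by a count ratio of 13.2 and stood at 0.72 ± 0.38 log2 in wild type (edgeR adjusted p = 0.156). Over the list alone 2 glue genes were higher and 1 heat shock gene was lower, and 0 genes of the other lists were called adjusted over the list alone. The T4/T5 neuron identity factors (median -0.13) had adjusted p = 0.833, and the Notch pathway genes (-0.22) 0.149. Of the other lists not called, median and mean differed in sign for the neurotransmitter (0.03 and -0.04), glial (0.04 and -0.03), apoptosis (0.04 and -0.00), heat shock (0.00 and -0.18) and antimicrobial peptide lists (0.34 and -0.40).

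Only the glue list kept its call in this comparison whichever library was left out, and with 1 run per library it too was not called (0.217), nor were the photoreceptor (0.0582) and neuronal (0.051) lists. The glue list had 1 member at 0 counts in ato input, and Sgs7 held few counts there. Its median in the interaction was not placed at a bound and may depend on the prior count. With DESeq2 size factors the synaptic and neuronal lists were not called (0.0602 both), nor were they with library totals (0.0719 both), and with the length correction the ribosomal list was not (0.151). Without wild-type IP 2 the cell cycle (0.146), synaptic (0.102), dpr, DIP, beat and side (0.077) and photoreceptor (0.0895) lists were not called, and the ribosomal protein genes turned to a median of 0.06 (0.223). Without ato IP 2 the cell cycle (0.0609), neuronal cell body (0.189), synaptic (0.0609), photoreceptor (0.188) and muscle (0.896) lists were lost. Without ato IP 1 the neuronal (0.108), synaptic (0.303), dpr, DIP, beat and side (0.245) and ribosomal (0.174) lists were lost, and without wild-type IP 1 the neuronal (0.278), synaptic (0.0677) and muscle (0.123) lists. Without wild-type input 1 the neuronal (0.0535), synaptic (0.317) and dpr, DIP, beat and side (0.0535) lists were lost, and without wild-type input 2 the neuronal (0.136) and ribosomal (0.0717) lists. Without ato input 1 the muscle (0.683) and ribosomal (0.698) lists were lost, and without ato input 2 the neuronal (0.224), synaptic (0.744, median 0.04) and dpr, DIP, beat and side (0.224) lists.

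**Figure D4:**
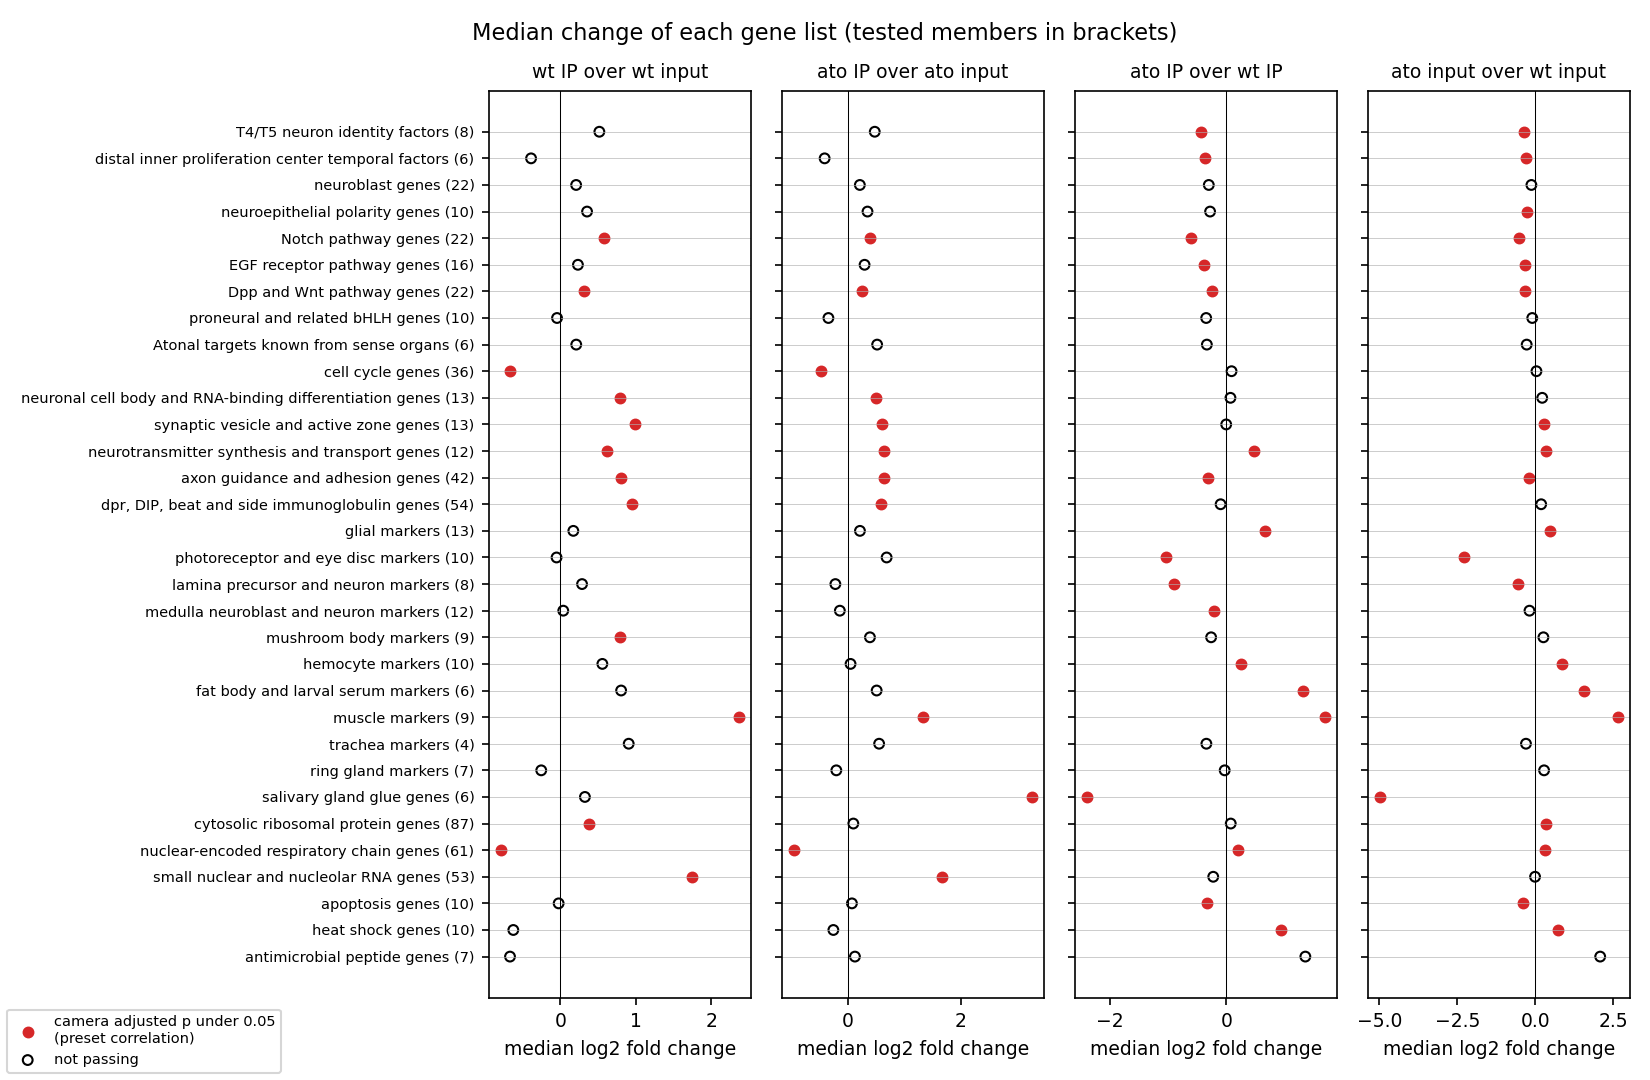
Median log2 fold change (x axis, a different scale in each panel) of each of the 32 gene lists (y axis, tested members in brackets) in 4 comparisons, filled where the camera adjusted p is below 0.05 with the preset correlation. Muscle markers lie at 2.37 and 1.33 in IP over input and at 1.69 and 2.65 in ato over wild type, while photoreceptor markers lie at -1.03 in the IPs and -2.29 in the inputs.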

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

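The tests of the slopes, of marker removal, of length as the whole cause, of attached tissue, of long noncoding RNA and of calls on chromosome 3 were chosen only after the results they bear on were seen, and so was the list of ecdysone response genes.

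In 8 lists the IP-over-input ratio differed between genotypes by an interaction test (camera, preset correlation), and in 0 of them with an estimated correlation. Cell cycle genes (median 0.149), photoreceptor markers (0.824) and salivary gland glue genes (2.69) lay higher in ato. The glue value may depend on the prior count, since a member had 0 counts in ato input. Muscle markers (-0.825), the dpr, DIP, beat and side genes (-0.374), ribosomal protein genes (-0.29), synaptic genes (-0.229) and neuronal cell body genes (-0.2) lay lower. All of these lists but the glue list lost the call when a single library was left out, such as the muscle list (adjusted p = 0.896 without ato IP 2), the synaptic list (0.744 without ato input 2) and the ribosomal list (0.223 without wild-type IP 2, where its median turned to 0.0583), and the glue list lost it with 1 run per library (0.217). No single gene of these lists passed the all-gene threshold of edgeR, where 436 of all genes had an unadjusted p below 0.05, while limma-voom called 0 genes and the DESeq2 Wald test 1 gene, CG7888, outside these lists. With the homogenate as a block 10 genes were called lower, all outside these lists, and the neuronal cell body list was not called (0.051).

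Genotype differences in whole-brain RNA reappeared in part in the IP, where 333 of the 713 genes called between inputs were called too, with gl, eya and HLHmgamma lower and Gs2, Mlc1 and Hsp68 higher in both. The slope of the IP change on the input change was 0.594 (0.541 to 0.649) over the genes called between inputs, a value that RNA of cells outside the driver staying in the IP may give. Removal of muscle markers by the IP is argued against, since all 9 were higher in the wild-type IP, with a median of 2.37 (1.60 to 3.40). On average these markers lay above the lowest abundance bin, at a mean log2 CPM of 3.21 and 3.07 in wild-type inputs. Whether the IP removed glial and photoreceptor markers cannot be told from their medians in wild type. These were 0.17 for glial and -0.049 (-0.41 to 0.564) for photoreceptor markers. The wild-type ratio of IP over input also moved with abundance. Its median was 2.23 over genes of 0.339 to 2.52 mean CPM and -0.2 over genes of 55.5 to 113 mean CPM. The markers were not compared with sets matched on length and expression. A change confined to the driver's cells would be at least as large in the IP as in the input, and this cannot be told apart, since the slope moved with the genes chosen. Over the genes called between inputs it was 0.594, and 0.794 (0.764 to 0.824) over those of them with every group mean above 5 CPM. Over the genes called between IPs it was 0.851 (0.783 to 0.924), and 0.974 (0.941 to 1.01) over those of them with every group mean above 5 CPM. Only the last interval spans 1, and the others lie below it. Each set was chosen by its change in a single fraction, which can itself move the slope. An effect of the genotype stays open.

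Some long and neuronal transcripts such as cac, para and Ten-a were higher in the IP. Length as the whole cause is argued against, since 85.6% (83.9 to 87.2) of the genes called higher in wild type were still called after the length correction, with a median log2 of 1.54 before and 1.36 after it. The 121 neuronal members had a median of 0.825, at percentile 100 of sets matched on length and expression (0.116 to 0.41), and the 54 long noncoding RNA genes had 1.70, also at percentile 100 of matched protein-coding sets (0.116 to 0.982). The IP may thus hold RNA that is not translated beside neuronal transcripts. How much of the enrichment stems from ribosomes of the driver's cells stays open, since no IP without the tagged protein is among the libraries.

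Muscle, fat body, glue and heat shock genes differed between genotypes in the inputs, with Mlc1 and Hsp68 higher and Sgs7 lower in ato. An excess of calls near ato over all other genes is argued against, as a call within 5 Mb of ato had an odds ratio of 0.989 (0.741 to 1.30), although Hsp70Ba and Hsp70Bc lie there. In that window 6.91% of the genes were called. The other genes include the rest of chromosome 3, so the test does not bear on variants carried elsewhere on the ato1 chromosome. Tissue attached in 1 ato preparation alone is argued against for muscle, since both ato inputs (mean log2 CPM of markers 5.61 and 4.82) lay above both wild-type inputs (3.21 and 3.07). Uneven amounts attached to both ato preparations cannot be told apart with 2 libraries per group. The ato inputs differed by 0.796 log2 and the wild-type inputs by 0.148. The gap between the ato inputs was 38.3% (33.5 to 44.6, over markers) of the genotype difference. A lag in development may lower ecdysone response genes, whose median was -0.435 (-0.894 to -0.04) with some members higher, and this cannot be told apart from other causes because the interval spans both predicted ranges. Variants elsewhere on chromosome 3, where 8.86% of the genes were called against 5.77% on the other chromosomes (odds ratio 1.59, 1.35 to 1.87), a difference in dissection or handling between all wild-type and all ato preparations, and an effect of the genotype, stay open.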

How the results depend on the processing

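The tests with counts halved and with the length correction were chosen only after the data were seen. Gene counts stayed within 1.5 times their value except as follows, and the cause was not tested beyond the fewer or more genes or libraries that an alternative holds. With no low-count filter, which tests more genes, 452 genes were higher and 356 lower between IPs, 390 lower between inputs and 9 lower in the interaction. With only the groups compared 114 were lower between IPs, and with 1 run per library 157 were lower between inputs. In the interaction the DESeq2 Wald test called 1 gene lower and the homogenate block 10. Leaving out each library gave 903 to 1494 genes higher and 1162 to 1630 lower for IP against input in wild type, 617 to 853 and 1022 to 1432 in ato, 179 to 242 and 55 to 196 between IPs, 239 to 366 and 82 to 243 between inputs, and 0 to 3 lower in the interaction. With these fewer libraries the sign turned for RpL10Ab between IPs (-0.1902 to 0.47, with -0.06043 without ato IP 2) and in the interaction (-0.4628 to 0.2081, with 0.04176 without ato input 1 and 0.05274 without ato IP 1), for ato in the wild-type IP against input (-0.007643 to 0.4014) and for the ribosomal protein list in the interaction (-0.539 to 0.05833). The median also turned for the synaptic list in the interaction without ato input 2 (0.04319) and for the respiratory list between IPs without wild-type IP 1 (-0.004263), and for the axon guidance list between inputs with the length correction (0.0303). The length correction turned sdt (-0.154), Dscam (-0.2085) and trio (-0.2667) in the ato IP against input. Camera with an estimated correlation ended all 71 list calls, also where the estimate lay below the preset 0.01. Examples are the Notch pathway genes between IPs (0.00899) and the neuronal cell body genes in wild type (-0.0453). A higher correlation among members therefore cannot be the only cause of these losses. The estimated form also tests on far fewer degrees of freedom, those left by 8 libraries in 4 groups. Its losses therefore do not measure correlation alone. The length correction ended 16 of 71 list calls. It also ended the calls of 10 of 113 named genes in the wild-type IP against input, 22 of 105 in the ato IP against input, 3 of 64 between IPs and 10 of 76 between inputs. Leaving out a library ended the calls of more of these named genes, 18 of 113, 39 of 105, 31 of 64 and 47 of 76 in the same order, and 90, 55, 29 and 25 kept their call under every alternative. Beside the genes of the interaction, the block changed the call of the Atonal targets list between inputs (adjusted p = 0.0407), of the neuronal cell body list in the interaction (0.051), and of DptB (0.0533), Sgs8 (0.0551) and CG18624 (0.0512), and no other call of a list or named gene. With 7780123 to 12238648 counts per library and 2 libraries per group, the interaction is limited most, since 18.5% of simulated changes of 2-fold were recovered.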

Other observations

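The lists of glycolysis and lactate genes, glutathione S-transferase genes and ecdysone response genes, and the transcript classes, were chosen only after the results were seen.

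Most of the glycolysis and lactate genes listed were higher in ato in both fractions. The lactate dehydrogenase gene ImpL3, now Ldh, was higher by log2 4.15 ± 0.23 (SE, n = 2 libraries per group) in the IPs and 4.04 ± 0.22 in the inputs (edgeR adjusted p = 1.5e-08 in both). Of the 15 genes, 12 were higher and 0 lower in the IPs (14 adjusted over the list alone) and 13 and 0 in the inputs (14 adjusted over the list alone), among them Ald (1.73 ± 0.17 and 1.55 ± 0.17), Pglym78 (1.61 ± 0.16 and 1.61 ± 0.16) and Tret1-1 (2.01 ± 0.24 and 1.72 ± 0.23). ImpL3 had the smallest p of all genes in both comparisons, and the list was chosen after that, so no list test between genotypes is given. In the wild-type IP 10 of the 15 were lower than in its input (11 adjusted over the list alone, camera adjusted p = 0.000343, and adjusted p = 0.242 with an estimated correlation), and in the ato IP 6 (7 adjusted over the list alone, 0.0078, and adjusted p = 0.316 with an estimated correlation). In the interaction 0 members were called, with a median of 0.146 (camera adjusted p = 0.0103, and adjusted p = 0.439 with an estimated correlation).

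Glutathione S-transferase genes were higher in 5 of 31 in the IPs (7 adjusted over the list alone) and in 8 of 31 in the inputs (9 adjusted over the list alone), such as GstE1 (2.21 ± 0.21 and 1.77 ± 0.20). Of 17 ecdysone response genes 7 were lower in the IPs (9 lower and 3 higher adjusted over the list alone), among them Eip74EF (-1.17 ± 0.19) and ImpE2 (-1.05 ± 0.20). In the inputs 5 were lower and 2 higher, ftz-f1 (1.72 ± 0.37) and ImpL1 (2.83 ± 0.62), with 7 and 2 adjusted over the list alone.

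The 54 long noncoding RNA genes had a median of 1.70 in wild type, with 24 higher and 1 lower, and 20 higher and 1 lower in ato. The 45 small nucleolar RNA genes had medians of 1.62 in wild type and 1.67 in ato (8 and 8 higher), the 9926 protein-coding genes 0.05 and 0.01, and the 1704 genes with the lowest mean CPM of any class 2.23 and 1.59. The noncoding RNA noe, named after its values were seen, had the largest count in each IP and was higher there by 1.82 ± 0.23 in wild type and 1.39 ± 0.23 in ato.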
